A study of Homo sapiens with 2 samples.

How the data were processed

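RNA was measured in 2 libraries of the SNU449 cell line, 1 with an FZD2 shRNA and 1 with a control shRNA, 7 days after lentiviral transduction. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented and reverse transcribed with random primers, and per the series design it was sequenced on a BGISEQ-500. The submitters' processing notes name Bowtie2, HISAT and the genome build hg19, without versions or roles. The counting program, the gene annotation and the strand setting are not given in the sources used here.

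The deposited files list, per the file headers, an expected count, an FPKM value and a length for each gene. The expected counts deposited by the authors are estimated reads per gene, which need not be whole and are not normalized. The deposited FPKM values are scaled by the authors to gene length and library size. Genes at 0 are unlisted and were set to 0. The files gave gene identifiers, and symbols were taken from the RefSeq gene table supplied with the reference. Of the measured genes, 53 had no symbol and were counted but never named. The reference annotation was of another build than the authors', so no coordinates are given.

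The main measure was log2((FPKM + 1) / (FPKM + 1)), FZD2 shRNA over control, with a pseudocount of 1 FPKM and no further scaling. A fold on this scale understates the difference of low genes. A gene was measured at an FPKM of at least 1 in at least 1 library, and called higher or lower at a log2 ratio of 1 or more in size. With 1 library per group, no test of the conditions was possible and no p-value is given. The 95% interval of a count ratio is the exact conditional binomial interval on the expected counts rounded to whole numbers and scaled to the library totals. It covers counting error only, and takes each read as independent. Reads copied in amplification are not independent molecules, so it can be too narrow even for counting error. Totals of 8234592 (FZD2 shRNA) and 8436870 (control) expected counts set this precision, and 3 counts are 3.64e-05% and 3.56e-05% of them.

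Gene lists (41, with 930 entries) were fixed before the data were examined. A list's median was placed as a percentile among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. This describes the 2 libraries and is not a p-value. The named genes were FZD2, then the 12 highest and 12 lowest genes with at least 5 FPKM in the higher library, then up to 4 measured members per list with the largest log2 ratio in size, and every frizzled receptor. Other genes named were chosen after their values were seen: the set without shared reads and with at least 50 reads, abundant RNAs, and some further members of lists. Some genes that the rule would name are not reported here.

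A gene was said to have shared reads if its expected count was not whole, to a tolerance of 0.001, in either library. GC content and the Alu-like share of transcripts were computed on GENCODE release 29 transcripts matched by RefSeq accession, which covered 96.1% of measured genes. Alu-like sequence was found with blastn 2.17.0 (word size 11, E-value at most 1e-05) using the 7SL RNA gene RN7SL1 as the query. A GC trend was fitted by lowess (fraction 0.3) to genes without shared reads and taken out in an added alternative.

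The count, interval and size rules were tested on simulated Poisson counts for this comparison, with 13991 genes measured. The size rule recovered 85.1% of genes changed 3-fold and 97.0% of those changed 6-fold, but 26.9% of those changed 2-fold, and it passed 118 of 13792 unchanged genes (0.856%). The simulation drew independent counts with a fixed length per gene. It held no variation between cultures or libraries, no GC trend and no shared reads, so 0.856% covers counting error only. Random lists fell outside the central range in 2 of 100 runs, and lists shifted by 0.5 in 53 of 100. Those lists were drawn at random from the measured genes, as were the lists they were placed among.

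Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, TPM, the median ratio set to 0, TMM scaling, counts scaled to CPM, size limits of 1.5-fold and 4-fold, a counting interval that excludes 1, random lists not matched on expression, and means in place of medians. Added after seeing the data were genes without shared reads, the GC trend taken out, genes without Alu-like sequence, genes with at least 50 reads, and random lists matched on GC. Where the GC trend was taken out, the random lists were matched on shared reads as well. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Biopython 1.88 and matplotlib 3.10.9.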

Results

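Poly(A)-selected RNA was sequenced from SNU449, an established human liver cancer cell line, 7 days after transduction with lentivirus expressing either a short hairpin RNA (shRNA) against FZD2 or a control shRNA. FZD2 is a frizzled receptor for Wnt ligands. Each group held 1 library, so no value below has a replicate error and no difference was tested for significance. Sizes are given as log2 ratios of FZD2 shRNA over control, computed on FPKM + 1. Intervals, where printed, are 95% intervals of the read counts of these 2 libraries. They cover counting error only, with each read taken as independent. The FZD2 shRNA library held 8234592 expected counts over 18303 listed genes, and the control library 8436870 over 18336. In all, 14377 genes reached an FPKM of at least 1 in at least 1 library and are called measured.

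The first question was whether the targeted transcript was lower. FZD2 (gene identifier 2535) was at 15.76 FPKM in the FZD2 shRNA library and 59.45 FPKM in the control library, a log2 ratio of -1.85, or 3.61-fold lower. Its expected counts were 503.28 and 1949.91, a count log2 ratio of -1.92 (-2.06 to -1.78). Neither count was whole, so some of its reads may have been shared with other genes, in a share that was not measured. The direction matched the labels.

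The other frizzled receptors had mixed values. Of the 10 receptors, 7 were measured, and besides FZD2 itself 2 were lower by at least 2-fold and 1 was higher. FZD5 was at 0.47 against 3.47 FPKM (log2 -1.60) and FZD6 at 3.37 against 9.73 (-1.30). FZD7 did not reach 2-fold, at 1.87 against 4.05 (-0.82). FZD3 was higher, at 5.62 against 1.77 (1.26), FZD4 was at 3.51 against 3.5, and FZD1 was at 0.63 against 1.06. With a pseudocount of 5, FZD5 (-0.63), FZD6 (-0.82) and FZD3 (0.65) fell short of 2-fold. The list's median was -0.82, at the 0.67th percentile of 10000 random lists matched on expression. That median includes FZD2 itself. Without FZD2, the median of the other 6 members was -0.58, at the 5.39th percentile, inside the central 95% of random lists. Of the 7 receptors, 6 had shared reads, so their values are uncertain.

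**Figure D1:**
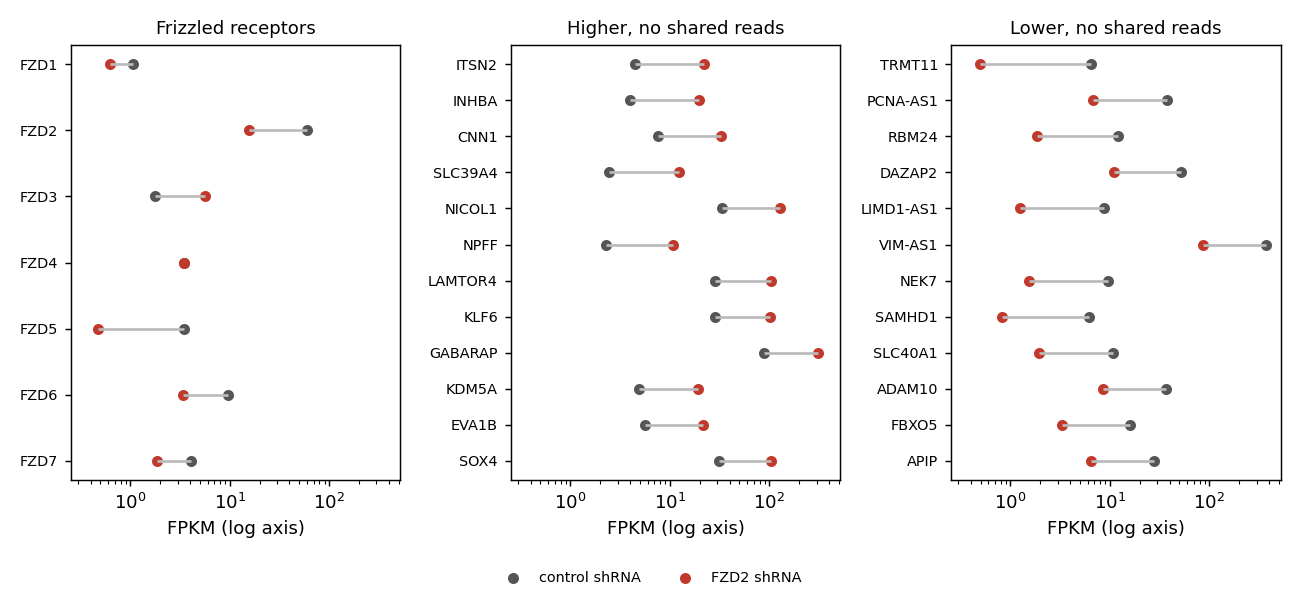
FPKM on a log axis in the control shRNA library (grey) and the FZD2 shRNA library (red), 1 library each, for the 7 measured frizzled receptors and for the 12 highest and 12 lowest genes without shared reads. FZD2 lay at 59.45 FPKM in the control and 15.76 FPKM in the FZD2 shRNA library.

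Across the transcriptome, 2188 measured genes were at least 2-fold higher in the FZD2 shRNA library, 1066 were at least 2-fold lower, and 11123 lay between. The direction split by whether a gene's reads were shared with other genes, read from an expected count that was not whole in either library. Among the 6223 genes with shared reads, 1846 were higher and 231 lower, with a median of 0.48. Among the 8154 genes without shared reads, 342 were higher and 835 lower, with a median of -0.25. Long noncoding RNA genes were 636 higher and 46 lower, but 30 higher and 28 lower when they had no shared reads. Protein-coding genes without shared reads were 242 higher and 702 lower.

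**Figure D2:**
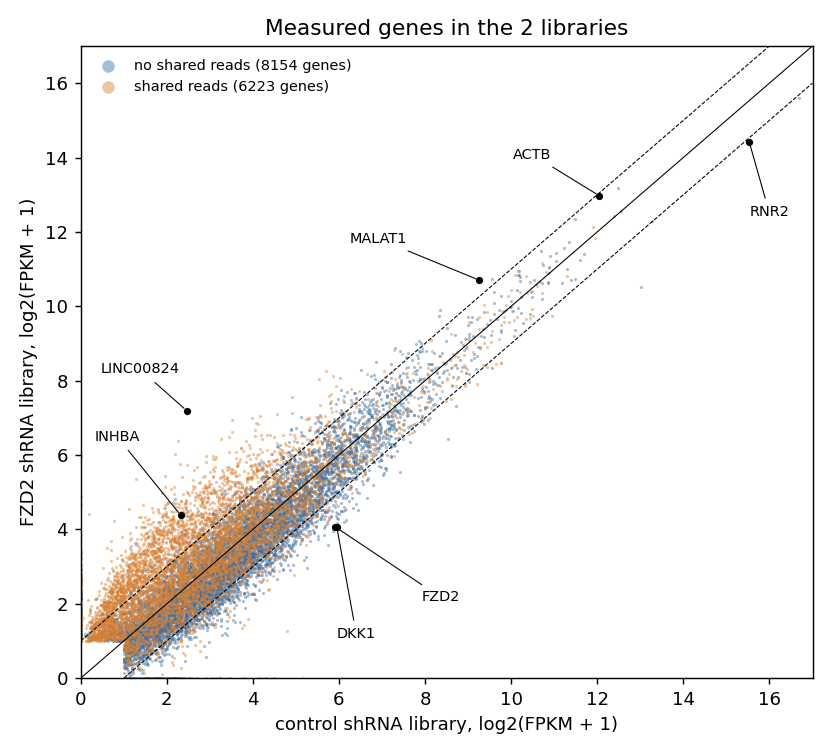
Level of each measured gene in the control shRNA library (x axis) and the FZD2 shRNA library (y axis), as log2(FPKM + 1), 1 point per gene. Solid and dashed lines mark equal levels and a 2-fold difference. Of the genes above the upper dashed line, 1846 of 2188 had shared reads (orange).

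The naming rule fixed before the data were examined picked, on the higher side, 12 genes that all had shared reads. LINC00824, a long noncoding RNA, was at 145.41 against 4.52 FPKM, FRMD6-AS1 at 82.92 against 3.81, LINC01551 at 40.02 against 1.43, and OTUD6A, a deubiquitinase gene, at 42.41 against 2.88. NANOGNB was at 17.86 against 0.72 FPKM. The others were the readthrough genes TNFAIP8L2-SCNM1 and ZFP91-CNTF, the small nucleolar RNA genes SNORA105A and SNORA105B, LOC102724874, TMEM183BP and SERF1A, several of which have near-identical or overlapping copies. On the lower side, 10 of the 12 were small RNA genes with fewer than 15 expected counts in the control library (MIR3655, MIR6835, MIR24-1, SNORD73A, SNORD139, SNORD80, SNORD22, SNORD50B, SNORD52 and SNORD76), of which MIR3655 and SNORD22 alone stayed 2-fold lower in CPM. The remaining lower genes, NME1-NME2 (1.39 against 26.93 FPKM) and BIVM-ERCC5 (unlisted against 9.77 FPKM), are readthrough genes that overlap their parents.

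Because those genes rest on shared or few reads, a second set was chosen after the values were seen, limited to genes without shared reads, at least 50 reads and at least 5 FPKM. The higher genes were led by ITSN2, an endocytic scaffold (22.25 against 4.48 FPKM, log2 2.08), INHBA, the activin A subunit (19.87 against 4.01, 2.06), CNN1, a smooth-muscle calponin (32.44 against 7.55, 1.97), and SLC39A4, a zinc importer (12.42 against 2.45, 1.96). They also held the transcription factors KLF6 (102.04 against 28.49, 1.80) and SOX4 (105.25 against 31.2, 1.72), the histone demethylase KDM5A (19.13 against 4.86, 1.78) and the autophagy protein GABARAP (311.4 against 89.62, 1.79). NICOL1, NPFF, LAMTOR4 and EVA1B completed the 12. The lower genes included the tRNA methyltransferase gene TRMT11 (0.49 against 6.48, -2.33), RBM24 (1.86 against 12.07, -2.19), DAZAP2 (10.95 against 52.26, -2.16), the mitotic kinase NEK7 (1.54 against 9.52, -2.05), SAMHD1, a dNTP hydrolase (0.83 against 6.24, -1.98, or -0.95 with a pseudocount of 5), the iron exporter SLC40A1 (1.96 against 10.7, -1.98) and the sheddase ADAM10 (8.61 against 36.61, -1.97). FBXO5 and APIP were also lower. PCNA-AS1, VIM-AS1 and LIMD1-AS1 were lower too, but they are antisense genes, and the strand used in counting is not given in the sources used here.

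The study's question concerned FZD2 signalling in liver cancer cells, and 41 gene lists were fixed before the data were examined. Of 40 that could be placed, 11 had medians below the central 95% of random lists matched on expression and 1 lay above it. The 11 include the frizzled list, which was inside without FZD2. These random lists were not matched on shared reads or GC content, with which the ratios also moved, and on genes without shared reads matched on GC 5 lists lay below. The mitochondrial genome list had 0 measured members. Of 108 list members past 2-fold, 24 of the 106 with known GC content fell short of it with the GC trend taken out, 15 in TPM and 51 with a pseudocount of 5. Among the 51 are genes named below without that value, such as CHAC1 (-0.60), WNT3 (-0.50), BMI1 (-0.55), DAAM1 (0.61), RFC3 (-0.90) and ASNS (-0.84).

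Wnt/beta-catenin target genes did not stand apart as a list. Of 14 measured, 2 were lower and 0 higher, with a median of -0.10 at the 34.1st percentile. DKK1, a secreted Wnt antagonist, was at 15.78 against 60.8 FPKM (-1.88), and the transcription factor gene MYC at 25.28 against 65.44 (-1.34). AXIN2 was at 0.68 against 1.57 (-0.61) and NKD1 at 1.85 against 0.44 (0.98, shared reads). Of 19 measured Wnt co-receptor and non-canonical signalling genes, 1 was higher (DAAM1, 7.55 against 3.2) and 0 lower, yet the median was -0.53, at the 0.74th percentile (7.65th, inside the range, on genes without shared reads matched on GC). CAMK2D was at 7.03 against 14.82 (-0.98), and RAC1, a small GTPase, at 443.42 against 230.81 (0.94). Of 8 measured Wnt ligands, WNT9B (1.70, shared reads) and WNT5B (1.07, or 0.79 with the GC trend taken out) were higher and WNT3 lower (-1.33).

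Mesenchymal and epithelial markers both lay inside the range of random lists. Of 22 measured mesenchymal markers, 1 was higher and 2 lower (median -0.17, 20.1st percentile). TAGLN was at 166.01 against 59.71 FPKM (1.46), FOXC2 at 3.58 against 10.77 (-1.36, or -0.88 with a pseudocount of 5, shared reads) and VIM at 2409.71 against 3090.37 (-0.36). Of 14 measured epithelial markers, MUC1 alone passed 2-fold, at 6.71 against 1.81 (1.46, or 0.78 with a pseudocount of 5). CDH1, which encodes E-cadherin, was at 1.68 against 1.32 (0.21). The list's median was 0.17, at the 76.1st percentile, but -0.02 without shared reads and -0.20 with the GC trend taken out.

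Genes linked to vasculogenic mimicry, the formation of vessel-like channels by tumour cells, were lower as a list. Of 17 measured, 5 were at least 2-fold lower and 1 was higher, with a median of -0.68 at the 0.08th percentile. EPHA2, an ephrin receptor, was at 10.94 against 36.42 FPKM (-1.65), VEGFA at 8.06 against 25.79 (-1.56), HIF1A at 31.11 against 83.96 (-1.40) and PTK2, focal adhesion kinase, at 13.79 against 38.12 (-1.40). FLT1, a VEGF receptor with shared reads, was at 13.05 against 3.57 (1.62). EPHA2 and PTK2 had shared reads as well. Of 16 measured stem-cell markers, 3 were lower and 2 higher, with a median of -0.64 at the 0.09th percentile. ALDH1A3 (13.95 against 42.06, -1.53), MYC and BMI1 (0.97 against 3.77, -1.28, shared reads) were lower. NANOG (14.83 against 2.35, 2.24) and POU5F1 (39.96 against 9.61, 1.95) were higher, and both had shared reads, so their values are uncertain. The mean over the stem-cell list was -0.16, at the 11.01st percentile, inside the range.

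Hippo pathway genes and YAP/TAZ target genes lay inside the range of random lists. Of 21 measured core genes, 2 were lower and 0 were higher (median -0.32, 8.0th percentile). The lower ones were WWTR1, which encodes TAZ (20.15 against 47.81, -1.21, shared reads), and FAT1 (2.52 against 6.48, -1.09, or -0.94 with the GC trend taken out). WWTR1 had no known GC content, so the GC trend could not be taken out of its value. Of 21 measured YAP/TAZ targets, CCDC80 was higher (76.66 against 23.85, 1.64) and MYOF lower (21.89 against 69.38, -1.62), while CCN2 was at 32.43 against 45.68 (-0.48) and CCN1 at 135.06 against 193.58 (-0.52). The list's median was -0.12, at the 28.2nd percentile.

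Cell-cycle genes were lower as lists. Of 30 measured G2/M and mitosis genes, 6 were lower and 1 was higher, with a median of -0.64, below all 10000 random lists. Among the 6, BUB1 (-0.82), MAD2L1 (-0.91) and ANLN (-0.92) fell short of 2-fold with the GC trend taken out, and also in TPM. The mitotic kinesin KIF20A was at 7.51 against 23.67 FPKM (-1.54) and CDK1 at 21.01 against 49.92 (-1.21), whereas TOP2A was at 261.03 against 112.69 (1.20). Of 29 measured G1/S and replication genes, 4 were lower and 0 higher (median -0.60, 0.04th percentile), among them MCM2 (6.41 against 21.47, -1.60), RFC3 (2.47 against 8.98, -1.52) and PCNA (47.2 against 135.96, -1.51). On genes without shared reads matched on GC, the G1/S list stood at the 2.57th percentile, inside the range. The G2/M list stood at the 1.82nd there, just below the range.

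Genes of the ATF4 and amino acid response were lower as a list. Of 23 measured, 9 were lower and 0 higher, with a median of -0.65 at the 0.02nd percentile. PSAT1, of serine synthesis, was at 21.77 against 67.01 FPKM (-1.58), DDIT4 at 5.89 against 17.55 (-1.43), CHAC1 at 0.77 against 3.73 (-1.42) and ASNS, asparagine synthetase, at 7.25 against 16.96 (-1.12, or -0.95 with the GC trend taken out). ATF4 itself was at 248.35 against 335.5 (-0.43). Of 14 measured fatty acid synthesis genes, 3 were lower and 0 higher (median -0.61, 0.65th percentile), with ELOVL5 at 18.33 against 62.33 (-1.71). Of 20 immediate early genes, 3 were lower and 3 higher (median -0.48, 0.92nd percentile, with the mean at the 4.45th, inside the range). SPRY2 was at 4.29 against 11.68 (-1.26). NR4A1 (9.53 against 1.93, 1.85, shared reads), KLF6 and JUND (63.15 against 29.27, 1.08) were higher, although JUND fell to 0.39 with the GC trend taken out. Of 15 matrix proteases and inhibitors, ADAM10, ADAM9 (22.08 against 86.64, -1.92) and MMP14 (3.26 against 7.78, -1.04, or -0.98 in TPM) were lower (median -0.61, 0.42nd percentile). Of 33 oxidative phosphorylation genes, 4 were lower, including SDHB (18.4 against 53.64, -1.49), with a median of -0.34 at the 1.30th percentile. Among the 4, SDHD (-0.93, shared reads) and ATP5F1C (-0.96) fell short of 2-fold with the GC trend taken out, and also in TPM. The protease and oxidative phosphorylation lists lay inside the range with the GC trend taken out (2.53rd and 10.5th percentile) and on genes without shared reads matched on GC (5.86th and 8.19th). The fatty acid list stood at the 4.49th percentile in the latter placement.

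Actin cytoskeleton genes and targets of SRF, the serum response factor, were the list above the range of random lists matched on expression, a place that depended on the setting. Of 22 measured, 7 were higher and 0 lower, with a median of 0.39 at the 97.9th percentile. They were CNN1, CALD1 (73.38 against 22.8, 1.64), MYL9 (961.91 against 325.67, 1.56), TAGLN, ACTG2 (4.18 against 1.37, 1.13), PDLIM7 (109.77 against 53.18, 1.03) and CNN2 (273.37 against 133.64, 1.03, shared reads). With the GC trend taken out, PDLIM7 (0.54) and CNN2 (0.72) no longer reached 2-fold. ACTB was at 8020.57 against 4238.19 (0.92, shared reads), while TPM1 was at 326.64 against 487.12 (-0.58). The list stood inside the range against random lists not matched on expression (95.5th percentile) and with the GC trend taken out (93.1st, median 0.10), and above it on genes without shared reads matched on GC (99.8th, median 0.61).

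The 2 libraries also differed in composition, and gene levels moved with sequence features. Mitochondrial ribosomal RNA took 3.88% of the expected counts in the FZD2 shRNA library and 8.31% in the control. MALAT1, a nuclear long noncoding RNA, took 1.48% and 0.546%. Among genes with shared reads, the median log2 ratio was 0.08 without Alu-like sequence in the transcripts and 1.503 with over 10% of it. Among genes without shared reads, the median was -0.53 in the lowest of 10 bins of GC content and 0.24 in the highest (Spearman's rho across 7999 genes 0.36, where genes are not independent replicates). When placed on genes without shared reads against random lists matched on expression and GC, a check chosen after seeing the data, 5 of the 10 lower lists that could be placed lay below the range, namely vasculogenic mimicry, stem-cell, G2/M, ATF4 and immediate early genes. The frizzled list had too few such members. With the GC trend taken out over all members, also chosen after seeing the data, 9 of the 11 lay below, counting the frizzled list with FZD2 in it. Under that setting collagens, p53 targets and metallothioneins lay below as well, for 12 lists in all, and the actin list moved inside, so that 0 lay above.

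**Figure D3:**
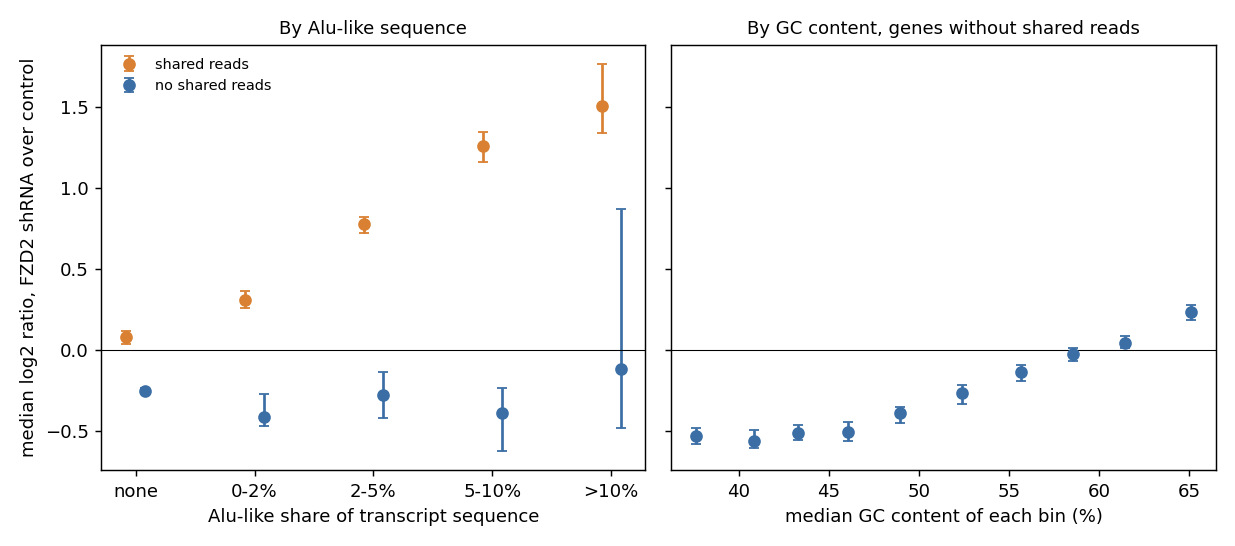
Median log2 ratio by the Alu-like share of transcript sequence (left), for genes with (orange) and without (blue) shared reads, and by GC content in 10 bins (right, percent, genes without shared reads). Bars are 95% intervals of the median across genes. Medians run from 0.08 to 1.503 on the left in orange and from -0.53 to 0.24 between the end bins on the right.

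Markers of other tissues were at varied levels. The growth protocol calls the cells prostate, while the cell type label says liver. Of 15 prostate markers, 9 were measured, the highest being PSCA (5.46 against 4.67 FPKM), and KLK4 was at 0.09 against 0.18. Of 28 hepatocyte markers, 7 were measured. ALB was at most 0.05 FPKM, whereas the fibrinogen genes FGG and FGB were at 123.36 against 100.72 and 105.3 against 91.67. Of 16 leukocyte markers, 4 were measured, with LYZ at 71.47 against 12.31 (2.44, shared reads). Of 14 endothelial markers, 4 were measured, 3 of them with shared reads (median 0.95, or 0.11 with no filter on low values), and of 15 fibroblast and stellate cell markers, 8 were measured, with COL1A2 at 198.48 against 306.36 FPKM, COL1A1 at 119.9 against 100.13 and RGS5 at 20.21 against 24.22 (median log2 ratio -0.01).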

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

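The tests on Alu repeats, expression bins, nuclear RNA, GC yield, transcript length and the actin members with or without shared reads were chosen after the results were seen. The olfactory receptor test and the GC tests of the whole ATF4 and actin lists were also added after the data and the patterns they address were seen, though before their own values were.

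The length column was not itself compared elsewhere, but FPKM is scaled to length, so lengths enter the main measure. The length listed for NEAT1 was 4.53-fold greater in the FZD2 shRNA library (22743 bases) than in the control (5021.62 bases). Its expected counts were 3.42-fold higher per library total, yet with the greater length its FPKM was lower (31.64 against 42.02). Of 8465 genes with at least 100 reads in both libraries, 1 had a listed length at least 2-fold greater and 2 at least 2-fold smaller.

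Genes with shared reads were higher in the FZD2 shRNA library, and 3 explanations were weighed. Reads from Alu repeats may contribute. Among genes with shared reads, those with at least 5% Alu-like sequence had a median 1.21 above those with none. Among genes without shared reads the difference was -0.12, with 65 genes at 5% or more. That second value adds little, because a gene that takes up ambiguous reads tends to get a count that is not whole and so leaves the group. For genomic DNA, the olfactory receptor test decided nothing, with 7 and 4 reads and a ratio of 1.79 (0.456 to 8.35). A later test argued against it among measured coding genes without shared reads. Those in the lowest of 4 expression bins had a median log2 count ratio of -0.51 and those in the highest bin -0.12. Added DNA needs a difference above 0, and it was -0.40, though another trend with expression could offset it. Coding genes with at most 10 reads, where added DNA would weigh most, had a pooled ratio of 0.936 (0.890 to 0.984), scaled to library totals. That is below 1, but it does not continue the fall towards low expression. A pooled ratio is also unlike those medians, so genomic DNA was not excluded. For more nuclear RNA, the median count log2 ratio of 7 nuclear long noncoding RNAs was 1.74 above that of 8 cytoplasmic ones, but this decides nothing, because 5 of the 7 had shared reads against 1 of the 8. The nuclear members without shared reads, MALAT1 (1.44) and TUG1 (-0.22), went opposite ways. An effect of the knockdown is untested, because each group had 1 library.

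Among genes without shared reads, the log2 ratio was higher at higher GC content. Transcript length was argued against as the source, because the median rho with GC over 8 length bins was 0.35, although the longest bin had 0.12. A GC-dependent yield of the libraries may be the source, since rho was at least 0.31 in each of 4 expression bins, but that test cannot separate it from GC-linked regulation after the knockdown.

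The ATF4 list was lower and the actin list higher, and the GC trend was weighed as the cause. With the trend taken out, the ATF4 median was -0.78, below the central 95% of matched random lists (-0.49 to 0.11), which argues against GC as its whole cause. For the actin list the median fell from 0.39, above its range (-0.34 to 0.37), to an adjusted 0.10 inside the range (-0.42 to 0.18). The second range was matched on shared reads as well as GC. GC or read sharing may thus account for the place of the whole actin list. Split afterwards, its members without shared reads had a median of 0.61, above the range of lists matched on GC (-0.32 to 0.41), while those with shared reads had an adjusted median of -0.27 inside theirs (-0.48 to 0.79). The 15 ATF4 members without shared reads had a median of -0.87, below their range (-0.57 to 0.13), which argues against read sharing as the cause there, and an effect of the knockdown stays untested beside a difference between the libraries.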

How the results depend on the processing

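FZD2 was lower under every alternative run, from -1.63 (pseudocount 5) to -2.36 (GC trend taken out). Genes higher numbered 941 with a pseudocount of 5, 342 without shared reads, 683 without Alu-like sequence, and 3747 and 382 at size limits of 1.5-fold and 4-fold. Genes lower numbered 1749 and 301 with pseudocounts of 0.1 and 5, and 3117 and 59 at the 2 size limits. Leaving out genes with shared reads thus turned the balance from 67.2% to 29.1% of calls on the higher side. TPM moved the median of all genes by 0.14. Each list's main median was given a 95% interval over its members. For short lists it spans nearly all members (-1.33 to 1.70 for Wnt ligands), so a value inside it shows little. Of the list medians, 504 of 511 alternative values stayed within that interval. The others were type I interferon (-0.53 without shared reads), ribosomal proteins (0.025 in TPM), prostate markers (1.00 with a pseudocount of 0.1, 0.91 in TPM and 1.10 in CPM, against a main value of 0.64) and endothelial markers (0.50 with a pseudocount of 5, 0.11 with no filter). Leaving out genes with shared reads changed the sign for prostate markers (-0.10), NRF2 targets (-0.27), epithelial markers (-0.02), type I interferon and ribosomal proteins (0.008). Other settings turned the sign for Wnt ligands (0.06 with no filter, 1.07 at 5 FPKM, 0.03 as a mean), histones (-0.42 at 50 reads), Notch (0.25 at 5 FPKM) and, in TPM among others, some lists with medians near 0. For single genes outside FZD2, shifts from the main value were set against the distance from the middle of their counting interval to its edge. The shift was larger in 239 cases and not larger in 1794. A gene unlisted in 1 library has an open-ended interval, so no shift can exceed that distance. Such genes include 11 of the 12 lower and 6 of the 12 higher genes picked by the naming rule. Any such case among the 1794 shows nothing about stability. Of 108 list members past 2-fold, those that fell short numbered 51 with a pseudocount of 5, 24 of 106 with the GC trend taken out, 15 in TPM, 5 with the median ratio set to 0, 3 in CPM and 2 with TMM, and 0 changed direction. List percentiles crossed an edge of the central 95% in 17 of 156 cases. With means these were stem-cell 11.01, immediate early 4.45, collagens 0.23, p53 targets 0.76 and unfolded protein response 0.50. With unmatched lists it was actin 95.5. With the GC trend taken out they were actin 93.1, matrix proteases 2.53, oxidative phosphorylation 10.5, collagens 1.89, p53 targets 1.67 and metallothioneins 2.33. On genes without shared reads matched on GC they were Wnt co-receptors 7.65, matrix proteases 5.86, G1/S 2.57, fatty acid synthesis 4.49 and oxidative phosphorylation 8.19. Fewer genes enter these last placements, and otherwise the cause was not tested. The settings on shared reads, Alu-like sequence, GC and 50 reads were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Depth limits the small RNA genes, 10 of which were named as lower on fewer than 15 counts.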

Other observations

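Other gene groups gave these values. Of 24 measured collagen and matrix genes, 2 were at least 2-fold lower and 0 higher (median -0.34, 3.39th percentile), with NID1, a basement membrane protein, at 7.32 against 27.29 FPKM and THBS1, thrombospondin, at 20.24 against 63.41. Of 14 integrins, ITGB1 (238.35 against 585.33, shared reads), ITGAV and ITGA6 were lower and ITGA8 (shared reads) higher. Those past 2-fold among 17 TGF-beta and BMP targets included INHBA and TGFB1I1 (80.74 against 27.81), which were higher, and SMAD7 (1.58 against 6.67) and BHLHE40, which were lower. Of 24 NF-kappaB and cytokine genes, 1 was higher and 4 lower. CCL5 was at 303.41 against 51.3 FPKM, with shared reads, and CCL2 (24.66 against 83.54), CXCL8 (14.5 against 38.97), CXCL5 (0.14 against 1.33, shared reads) and NFKB1 (3.05 against 7.16) were lower. With the GC trend taken out, ITGAV (-0.94), ITGA6 (-0.90), CXCL5 (-0.83) and NFKB1 (-0.998) fell short of 2-fold. Of 26 interferon response genes, 4 were higher and 2 lower (XAF1 19.6 against 6.22, shared reads, and IFIT2 1.17 against 4.84). IFI27 (0.95), IRF7 (0.45) and IFIT5 (-0.81) fell short of 2-fold with the GC trend taken out. Of the interferon genes past 2-fold, all but XAF1 fell short with a pseudocount of 5.

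Other lists lay inside the central 95% of random lists. Their medians were -0.30 (integrins, and also p53 targets, where CCNG1 was at 17.33 against 68.21 FPKM), -0.34 (TGF-beta and BMP targets), -0.18 (NF-kappaB), 0.09 (interferon, but -0.53 over the 15 without shared reads), -0.25 (Wnt ligands, though the mean was 0.03), -0.15 (MHC class I), -0.02 (hypoxia and glycolysis), -0.19 (cholesterol synthesis), -0.38 (unfolded protein response), 0.10 (NRF2 targets, but -0.27 over the 12 without shared reads), -0.53 (metallothioneins, 4 measured), -0.28 (Notch pathway), -0.29 (BCL2 family), 0.38 (histones, but -0.42 over genes with at least 50 reads), -0.13 (ribosomal proteins, but 0.008 without shared reads), 0.20 (hepatocyte markers, 4 of 7 with shared reads), -0.20 (fetal liver and liver cancer markers), 0.64 (prostate markers, 5 of 9 with shared reads, and -0.10 over the 4 without) and 0.33 (leukocyte markers, 3 of 4 with shared reads).

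Several chromatin regulators stood among the highest genes without shared reads, including KDM5A and SMARCC1 (30.15 against 9.25 FPKM), so a list of 72 such genes was written after these were seen. The hypothesis was that the class as a whole may be higher. Of 72 measured, 15 were higher and 2 lower, and the median of 0.15 lay inside the central 95% of random lists (-0.24 to 0.22). The 53 members without shared reads had a median of -0.0031, at the 99.9th percentile of lists matched on expression and GC. The placements disagree, and the list was built around genes already seen to be higher, so the test leaves the hypothesis open.

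CAPN12 was at 360.93 against 114.49 FPKM without shared reads, and GAPDH at 3422.54 against 2597.18. Coding genes with at most 10 reads over both libraries, without shared reads or Alu-like sequence, numbered 1776 and held 2926 and 3204 reads, a ratio, scaled to library totals, of 0.936 (0.890 to 0.984).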
